A study of Homo sapiens with 6 samples.

How the data were processed

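RNA was measured in BEAS-2B cells, an established human bronchial epithelial line, by total RNA extraction with TRIzol and sequencing of libraries made with the NEBNext Ultra RNA kit, per the labels' protocols. There were 6 libraries in 2 groups of 3. One group had received RSL3, a covalent inhibitor of GPX4 that is used to start ferroptosis, and the other RSL3 with indirubin (abbreviated ID). Per the labels' protocols RSL3 was given at 2 µM for 24 h, and indirubin was added 2 h earlier. The protocols give indirubin only as a range of 7.5 to 30 µM, so the dose of these libraries is not stated. Untreated cells, which the study's design text mentions, are not among the 6 samples, and neither are cells given indirubin alone. A changed response to RSL3 therefore cannot be told apart from an effect of indirubin itself.

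Groups were taken from the treatment field of the labels, because the titles of all 6 samples begin with RSL3+M, and M is not defined in the sources used here. The deposited tables are also titled RSL3+M, so that their second compound is indirubin rests on the treatment field alone. The columns of the expression table were assigned to groups by their names alone. 3 columns are named for RSL3. The other 3 add a garbled word to RSL3, which reads as "drug given" in Chinese when its encoding is repaired, and these were taken as RSL3+ID. The names do not tie a column to a single sample, so the libraries are numbered as in the columns. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

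The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, StringTie 2.1.5 and DESeq2 1.30.0 and the genome build GRCh38 (hg38), without saying what each tool was used for. The tool that counted the reads, its strand setting, the annotation and any filters are not given in the sources used here. Without a known strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart. Genes with near-identical copies, such as ribosomal protein genes, FTH1, metallothioneins and HSPA1A with HSPA1B, may share reads.

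The authors' deposited expression table holds log2 values for 35233 entries and 35019 Ensembl identifiers, and the 214 repeats of an identifier carried the same values and were left out. The values share one lowest value, 6.04, in all 6 columns, and their form is that of the variance-stabilising transform of DESeq2, the tool the authors list. The transform was inverted, which gave counts divided by a size factor. Their means matched the base mean, a signal column of the authors' deposited table of changed genes, within a relative difference of 2.5e-14 for 894 genes. After division by the step of each column, 100.0% of the values lay within 0.001 of a whole number of reads. That table of the authors also holds log2 fold changes with standard errors and p-values, per the file headers, for 895 genes, and its smaller companion keeps 153 genes of at least 2-fold. The sign of its fold change is that of RSL3+ID over RSL3, from the 894 genes that could be compared.

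The recovered reads on listed genes numbered between 15206183 and 18506637 per library. At this depth, 3 reads correspond to between 0.162 and 0.197 CPM (counts per 1e6 reads), the limit that a count of 0 allows. This limit covers counting error only, since reads without molecular identifiers are not independent molecules. Mitochondrially encoded genes are listed at 0 in every library and could not be tested.

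The tests planned before the data were examined were for counts. The plan's fallback, limma on log2 values, was meant for files that hold only length-scaled values (FPKM or TPM), with another filter. It was used here because the deposited values are log2 values, although whole reads could be recovered. Its use here and the filter below were therefore not planned. Normalised counts (counts divided by the authors' size factors) were tested as log2(normalised count + 1) with limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes step, and 2-sided p-values adjusted by Benjamini-Hochberg. The filter was a mean normalised count of at least 10 over the 6 libraries. Fold changes are on the log2(normalised count + 1) scale, which understates the change of low genes. Adjusted p-values in the text come from this limma test unless the authors' table is named. Deposited adjusted p-values of the authors come from DESeq2, per the file headers.

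31 gene lists were fixed before the data were examined. Lists with at least 5 tested members, 29 of them, were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera using an estimated correlation and fry as alternatives, and p-values were adjusted over the lists. For each list, the count of members past an adjusted p of 0.05 is given over all genes and adjusted over the list alone. The genes named in the text follow a rule fixed at the same time. It took 13 genes of ferroptosis, Wnt and aryl hydrocarbon receptor biology in all cases. It added the 7 largest rises and 7 largest falls among genes past an adjusted p of 0.05 with a mean of at least 5 CPM, a real gene symbol and no overlap between the groups. From each list it took up to 3 members past the threshold with the smallest p, or the member with the smallest p where none passed. Genes outside this rule are marked as chosen after their values were seen. This gave 64 genes, of which 1 among the 7 largest falls is not reported here.

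Gene positions, exon lengths and transcript lengths came from GENCODE 29 on GRCh38, matched by Ensembl identifier. The length of a gene's principal transcript is the median over its APPRIS principal transcripts, or over all its transcripts where none is marked. Matched genes came from the same quantile bin of length and of mean level as a list member, and their mean deviation was subtracted from that of the list in each library before the groups were compared by a pooled t interval with 4 degrees of freedom. Alternatives were other scalings, filters, a smaller pseudocount, the deposited values as they stand, limma-voom on the recovered reads, removal of a trend on exon length and GC content, a test against a fold of 1.5, the replicate number as a block, and leaving out each library in turn. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

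The steps were tested on simulated data for RSL3+ID versus RSL3, with reads drawn for the 14012 genes that passed the filter there. The test recovered 25.8% of genes changed by 1.5-fold, 60.0% of those changed by 2-fold and 83.3% of those changed by 4-fold. 5 of its 116 calls were false. In the simulated lists, camera called the list raised by 1.3-fold and 0 of 30 unchanged lists. The simulated genes were drawn independently, while real lists had estimated correlations such as 0.328 (ribosomal proteins) and 0.624 (heat shock). The simulation therefore does not show how often camera calls unchanged lists of correlated genes. The simulated libraries also carried no trend on transcript length or GC content. In the real libraries the correlation of a gene's deviation from its mean with exon length ran from −0.217 to 0.288. The shares of recovered genes and of false calls therefore need not hold for the real data.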

Results

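The transcriptome of BEAS-2B human bronchial epithelial cells was sequenced after treatment with RSL3, an inhibitor of the lipid peroxidase GPX4 that starts the iron-dependent cell death called ferroptosis, and after treatment with RSL3 and indirubin, a bis-indole dye that inhibits kinases including GSK-3β and binds the aryl hydrocarbon receptor. There were 3 libraries per group. The reads on listed genes numbered 17960356, 15206183 and 15292004 in the RSL3 libraries and 16065406, 16062502 and 18506637 in the RSL3+ID libraries. Between 18249 and 18995 genes had at least 1 read in a library, and the most abundant gene took at most 1.44% of the reads. Pearson correlations of log2 values were between 0.957 and 0.977 within groups and between 0.946 and 0.967 between groups. The groups separated on the first principal component of the 1000 most variable genes, which held 27.6% of the variance. RSL3+ID library 2 lay apart from the other libraries of its group on the second component (26.4% of the variance), at −31.3 against 15.4 and 1.37.

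**Figure D1:**
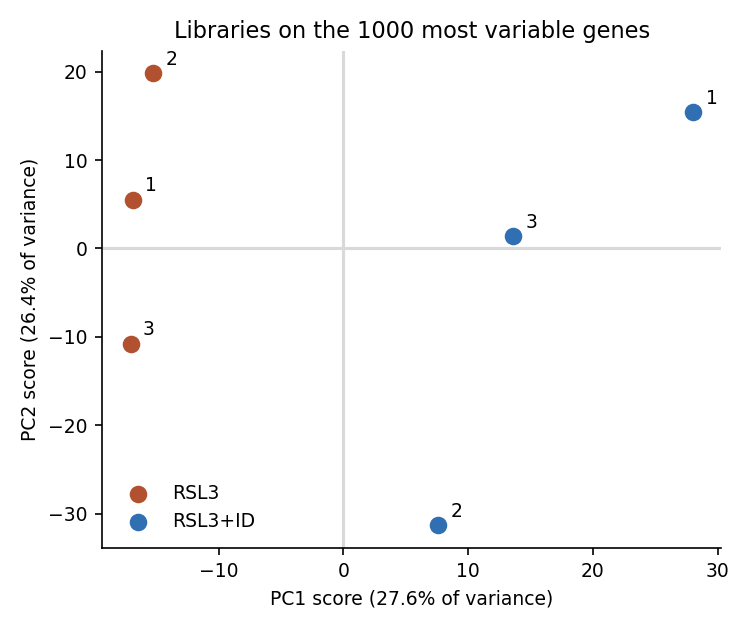
Scores of the 6 libraries on the first 2 principal components of the 1000 most variable genes, with the share of variance on each axis and the library number beside each point. The RSL3 libraries lie between −17.1 and −15.3 on the first component and the RSL3+ID libraries between 7.61 and 28.0, and RSL3+ID library 2 has the lowest score on the second.

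The comparison of RSL3+ID with RSL3 asks which transcripts differ when indirubin is present during GPX4 inhibition. Some highly expressed stress and iron genes were lower with indirubin, although iron genes as a list moved both ways. Of 22 tested genes of iron handling, 12 had positive and 10 negative estimates. HMOX1, the inducible heme oxygenase that releases iron from heme, fell from 20320 ± 2612 to 10540 ± 2393 normalised counts (mean ± SD, n = 3 per group), a log2 fold change of −0.97 (SE 0.17, adjusted p = 0.0291). FTH1, the iron-storing ferritin heavy chain, fell from 18520 ± 1855 to 10170 ± 804 (log2 fold change −0.86, SE 0.13, adjusted p = 0.0172). The small heat shock protein gene HSPB1 fell 1.85-fold, from 81580 ± 10220 to 44170 ± 5200 (adjusted p = 0.0184), and the metallothionein gene MT2A fell 2.01-fold, from 1747 ± 181 to 864.6 ± 32.7 (adjusted p = 0.0172). In the other direction ATF4, the transcription factor of the integrated stress response, rose 1.70-fold (adjusted p = 0.0247) and CDKN1A, the cell cycle inhibitor p21, rose 1.76-fold (adjusted p = 0.0172). Camera called neither the integrated stress response list nor the list of p53 targets that holds CDKN1A (adjusted p = 0.578 and 0.261). The former had 11 positive and 19 negative estimates and the latter 14 and 15.

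Of 14188 genes tested with limma, 153 were higher and 118 lower in RSL3+ID at an adjusted p under 0.05, and 37 and 47 of these differed by at least 2-fold. The smallest adjusted p was 0.00880, and 2744 genes had an unadjusted p under 0.05. The median fold of the higher genes was 1.70 and that of the lower genes 1.92. The count of 271 was 0, 3 and 3 without RSL3 library 1, 2 and 3, and 0, 1315 and 4 without RSL3+ID library 1, 2 and 3, with 270 of the 271 genes shared when RSL3+ID library 2 was left out. The higher genes made up 56.5% of the calls, against 29.3% with scaling to the total count, which moved the median log2 fold change of all genes to −0.11, and 73.8% with upper-quartile scaling.

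**Figure D2:**
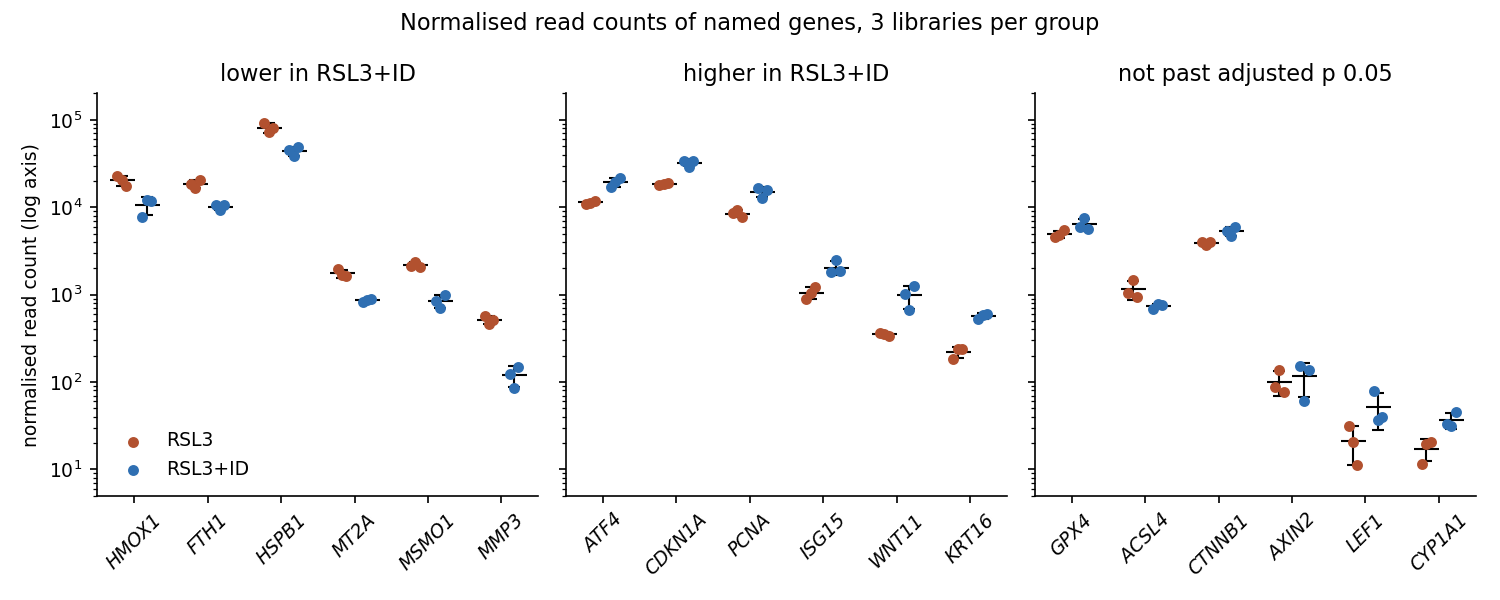
Normalised read counts (log axis) of 18 named genes in the 3 RSL3 libraries and the 3 RSL3+ID libraries, with points for libraries, a dash for the mean and bars for 1 SD. The panels hold genes that were lower, such as HMOX1 at 20320 against 10540, genes that were higher, such as ATF4 at 11320 against 19350, and genes that did not pass an adjusted p of 0.05, such as GPX4 at 4934 against 6383.

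The genes that act in ferroptosis itself mostly did not pass the test, as was true of all tested genes, of which 271 of 14188 passed. Of 28 tested drivers of ferroptosis, 1 fell, HMOX1, and 4 were lower when adjusted over the list alone. Of 34 tested suppressors, 2 fell, FTH1 and HSPB1, and 6 were lower when adjusted over the list alone. GPX4, the target of RSL3, had a log2 fold change of 0.36 (SE 0.15, adjusted p = 0.204), and SLC7A11, the cystine importer that feeds glutathione synthesis, one of −0.26 (SE 0.17, adjusted p = 0.441). ACSL4, which activates the polyunsaturated fatty acids that are peroxidised in ferroptosis, had 1153 ± 296 normalised counts with RSL3 and 735.9 ± 52.3 with RSL3+ID (log2 fold change −0.62, SE 0.19, adjusted p = 0.103). In the authors' deposited table ACSL4 passed, with a log2 fold change of −0.65 and an adjusted p of 0.0307. TFRC, the transferrin receptor, had a log2 fold change of 0.19 (SE 0.27, 95% confidence interval −0.40 to 0.77) and did not pass. It was −0.02 without RSL3+ID library 1 and 0.56 without RSL3+ID library 2, where it passed (adjusted p = 0.0391). Camera gave adjusted p = 0.394 for the drivers and 0.611 for the suppressors.

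Iron and antioxidant genes moved in both directions. Of 22 tested genes of iron handling, FTH1 and HMOX1 fell and HMOX2, the constitutive heme oxygenase, rose 1.79-fold (adjusted p = 0.0443); 2 were higher and 3 lower when adjusted over the list alone. Of 31 targets of NRF2, the regulator of antioxidant genes, 3 fell, namely FTH1, HMOX1 and the glutathione-conjugate exporter gene ABCC1 (log2 fold change −0.84, adjusted p = 0.0492), while 2 were higher and 4 lower when adjusted over the list alone. The median log2 fold change was 0.00 over the NRF2 list and 0.06 over the iron list, and camera called neither (adjusted p = 0.812 and 0.772). The median of the iron list was −0.02 without RSL3+ID library 1 and −0.05 without RSL3+ID library 3. In the list of metallothionein and metal response genes, with 7 tested, MT2A fell alone, and 2 were lower when adjusted over the list alone (camera adjusted p = 0.579). On GRCh38, HMOX1 (ENSG00000100292) spans chromosome 22 from 35380361 to 35394214, FTH1 (ENSG00000167996) chromosome 11 from 61959718 to 61967660, HSPB1 (ENSG00000106211) chromosome 7 from 76302544 to 76304295, and MT2A (ENSG00000125148) chromosome 16 from 56608199 to 56609497. All 4 are annotated as protein-coding genes, and each interval covers exons, introns and untranslated regions.

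The title of the series concerns Wnt/β-catenin signalling, so the genes of this pathway were examined as fixed lists. None of 18 tested direct targets of β-catenin passed over all genes, and 1 was lower when adjusted over the list alone, FOSL1, a subunit of the AP-1 transcription factor (log2 fold change −0.77, SE 0.20, adjusted p = 0.0743). In the authors' deposited table FOSL1 passed, with a log2 fold change of −0.72 and an adjusted p of 0.0166. The feedback inhibitor gene AXIN2 had 101.1 ± 31.9 normalised counts with RSL3 and 116.4 ± 48.9 with RSL3+ID, a log2 fold change of 0.14 with a 95% interval from −0.67 to 0.95, and its sign turned without RSL3 library 3 (−0.03) and without RSL3+ID library 1 (−0.10) or 3 (−0.04). LEF1, a transcription factor that partners β-catenin, had a log2 fold change of 1.27 (SE 0.49, adjusted p = 0.183) at 21.1 ± 9.97 and 51.8 ± 23.8 normalised counts. CTNNB1, which encodes β-catenin, had a log2 fold change of 0.44 (SE 0.14, adjusted p = 0.106), and GSK3B, the kinase that marks β-catenin for degradation, one of −0.28 (SE 0.17, adjusted p = 0.382). Among 35 tested pathway components, 1 fell, the adaptor gene DVL2 (log2 fold change −0.65, adjusted p = 0.0490), and 2 were lower when adjusted over the list alone. WNT11, a ligand that mostly acts outside the β-catenin branch, rose 2.68-fold. Camera gave adjusted p = 0.537 for the direct targets and 0.225 for the components. The median of the direct targets was −0.19, and with 1 library left out it ranged from −0.29 (without RSL3+ID library 1) to 0.00 (without RSL3+ID library 2, where camera's direction turned up, adjusted p = 0.551). The mean deviation of the direct targets from their level over all libraries, on the log2 scale, was −0.53 in RSL3+ID library 2 and 0.35 and 0.08 in libraries 1 and 3 of that group.

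None of 16 tested targets of the aryl hydrocarbon receptor passed over all genes or when adjusted over the list alone, and camera gave adjusted p = 0.645. The median of this list was 0.07, and it was −0.14 without RSL3+ID library 1, where camera's direction turned down (adjusted p = 0.866), 0.24 without RSL3+ID library 2 and −0.01 with scaling to the total count. CYP1A1, the receptor's best-known target and a xenobiotic-metabolising enzyme, had 17.3 ± 4.95 normalised counts with RSL3 and 36.6 ± 7.54 with RSL3+ID (log2 fold change 1.06, SE 0.45, adjusted p = 0.222). CYP1B1 had a log2 fold change of 0.54 (SE 0.22, adjusted p = 0.208), the receptor's repressor gene AHRR one of 0.29 (SE 0.23, adjusted p = 0.512), and STC2, which had the smallest p of the list, one of −0.44 (SE 0.13, adjusted p = 0.0846). In the authors' deposited table STC2 passed, with an adjusted p of 0.0383. STC2 also belongs to the integrated stress response list, as do SLC7A11 and SLC7A5, the latter named after its values were seen. The log2 fold changes of SLC7A11 and SLC7A5 were −0.26 and −0.37. The whole receptor list had 9 positive and 7 negative estimates.

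4 fixed lists were higher in RSL3+ID by camera. All 59 ribosomal protein genes had a positive estimate, with a median log2 fold change of 0.33; 3 rose over all genes (RPLP1, RPL26 and RPS9, by 1.56-, 1.53- and 1.48-fold) and 39 when adjusted over the list alone. Camera's adjusted p was 4.02e-19, against an adjusted p = 0.525 with an estimated correlation. Of 43 nuclear genes of oxidative phosphorylation, COX6C and NDUFB3, subunits of respiratory complexes, rose by 1.62- and 1.66-fold, and 5 were higher when adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 5.02e-06, and adjusted p = 0.635 with an estimated correlation). Of 38 genes of G1/S and DNA replication, PCNA, the sliding clamp of DNA polymerase, rose 1.77-fold, and 2 were higher when adjusted over the list alone (median 0.27, or 0.17 with scaling to the total count, camera adjusted p = 0.000596, and adjusted p = 0.525 with an estimated correlation). Of 29 interferon response genes, ISG15, a ubiquitin-like modifier, IRF7, a transcription factor of this response, and IFI6 rose by 1.94-, 1.75- and 1.81-fold, and 6 were higher when adjusted over the list alone (median 0.39, camera adjusted p = 0.00282, and adjusted p = 0.525 with an estimated correlation). The interferon median was 0.23 without RSL3+ID library 2 (adjusted p = 0.0111) and 0.14 on the deposited variance-stabilised values (adjusted p = 0.00276), where that of the ribosomal proteins was 0.33. The interferon genes deviated from their mean over all libraries by 0.25, 0.21 and −0.03 in RSL3+ID libraries 1, 2 and 3, and by −0.21, −0.13 and −0.09 in the RSL3 libraries. The share of reads on the ribosomal protein list was 7.25%, 7.07% and 7.89% in the RSL3 libraries and 8.68%, 9.23% and 8.88% in the RSL3+ID libraries.

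Fold change also followed transcript length. Across the 14188 tested genes, which are not independent replicates, the Spearman correlation of log2 fold change was −0.26 with exon length and −0.17 with the length of the principal transcript. Within groups the trend was uneven. The deviation of genes from their mean over all libraries correlated with exon length at 0.168, 0.288 and −0.011 in RSL3 libraries 1 to 3. In RSL3+ID libraries 1, 2 and 3 these values were −0.016, −0.217 and −0.19. With GC content the correlation ran from −0.239 in RSL3 library 2 to 0.231 in RSL3 library 3. Among the 2840 genes with the shortest principal transcripts (median 737 bp) 52 rose and 21 fell, and among the 2838 with the longest (median 5734 bp) 3 rose and 35 fell. The ribosomal protein and oxidative phosphorylation genes are short, with medians of 851 and 932 bp against 2202 bp over all tested genes. Removing a trend on exon length and GC content from each library left medians of 0.29 for the ribosomal proteins and 0.18 for oxidative phosphorylation.

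**Figure D3:**
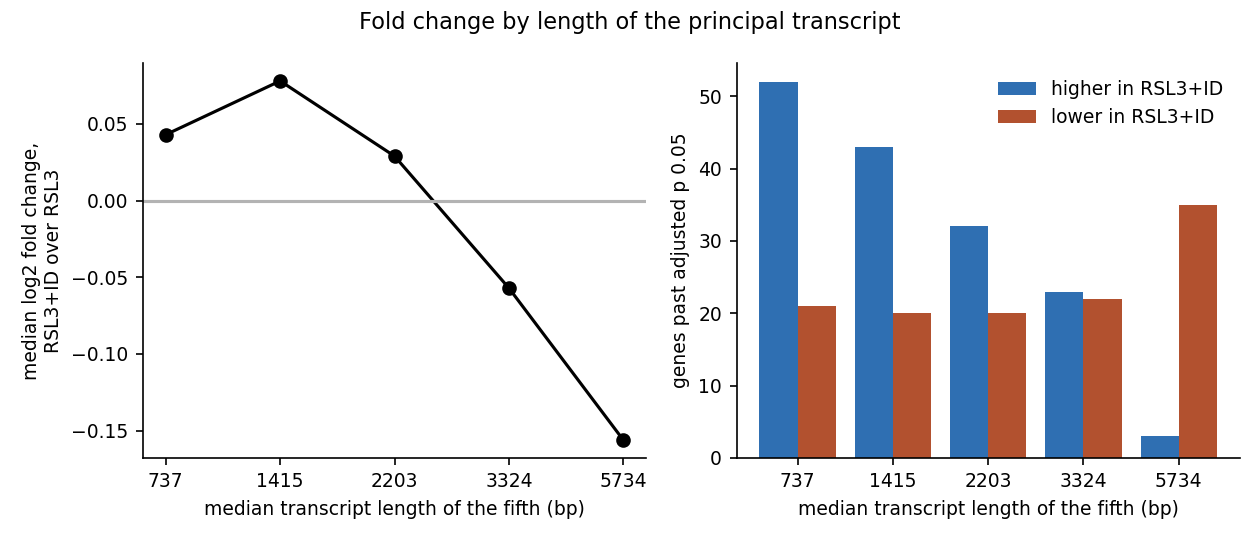
Left, median log2 fold change of RSL3+ID over RSL3 in 5 groups of between 2834 and 2840 genes ordered by the length of their principal transcript (median length in bp on the axis), and right, the number of genes past an adjusted p of 0.05 in each. The median is 0.04 in the shortest group and −0.16 in the longest, where 3 genes were higher and 35 lower.

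4 fixed lists were lower in RSL3+ID by camera. Of 25 genes of cholesterol synthesis, MSMO1, a sterol demethylation enzyme, fell 2.60-fold from 2187 ± 151 to 847.5 ± 150 normalised counts, and SREBF2, the transcription factor that drives this pathway, fell 1.99-fold, from 1965 ± 169 to 1004 ± 250. When adjusted over the list alone 11 were lower, and the median log2 fold change was −0.39 (camera adjusted p = 0.000558, and adjusted p = 0.525 with an estimated correlation). Of 26 genes of fatty acid and phospholipid synthesis none passed over all genes and 5 were lower when adjusted over the list alone, with SREBF1, a lipogenic transcription factor, at a log2 fold change of −0.80 (SE 0.21, adjusted p = 0.0727). The call of this list (camera adjusted p = 0.0199, and adjusted p = 0.635 with an estimated correlation) was lost without RSL3 library 2 (0.0582, with a median of −0.27 against −0.29) and without RSL3+ID library 2 (0.174, median −0.20), and its median moved to −0.17 with the length and GC trend removed. Of 22 heat shock genes HSPB1 fell, and 6 were lower when adjusted over the list alone (median −0.28, camera adjusted p = 0.00282, and adjusted p = 0.827 with an estimated correlation). Without RSL3+ID library 2, whose heat shock genes deviated from their mean over all libraries by −0.42 on the log2 scale, against −0.06 and 0.09 in libraries 1 and 3, the median was −0.14 and the adjusted p 0.205, and without RSL3 library 2 they were −0.16 and 0.0169. Of 29 genes of the TGF-β response and extracellular matrix, PMEPA1, a TGF-β-induced inhibitor of that pathway, fell 2.54-fold over all genes and when adjusted over the list alone (median −0.21, camera adjusted p = 0.0423, and adjusted p = 0.843 with an estimated correlation). This call was lost without RSL3 library 1 (0.172, median −0.15) or 2 (0.0895, median −0.19) and with the length and GC trend removed (0.186, median −0.11). The median was −0.37 without RSL3+ID library 1, turned to 0.05 without RSL3+ID library 2 (0.551) and was −0.14 on the deposited variance-stabilised values.

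**Figure D4:**
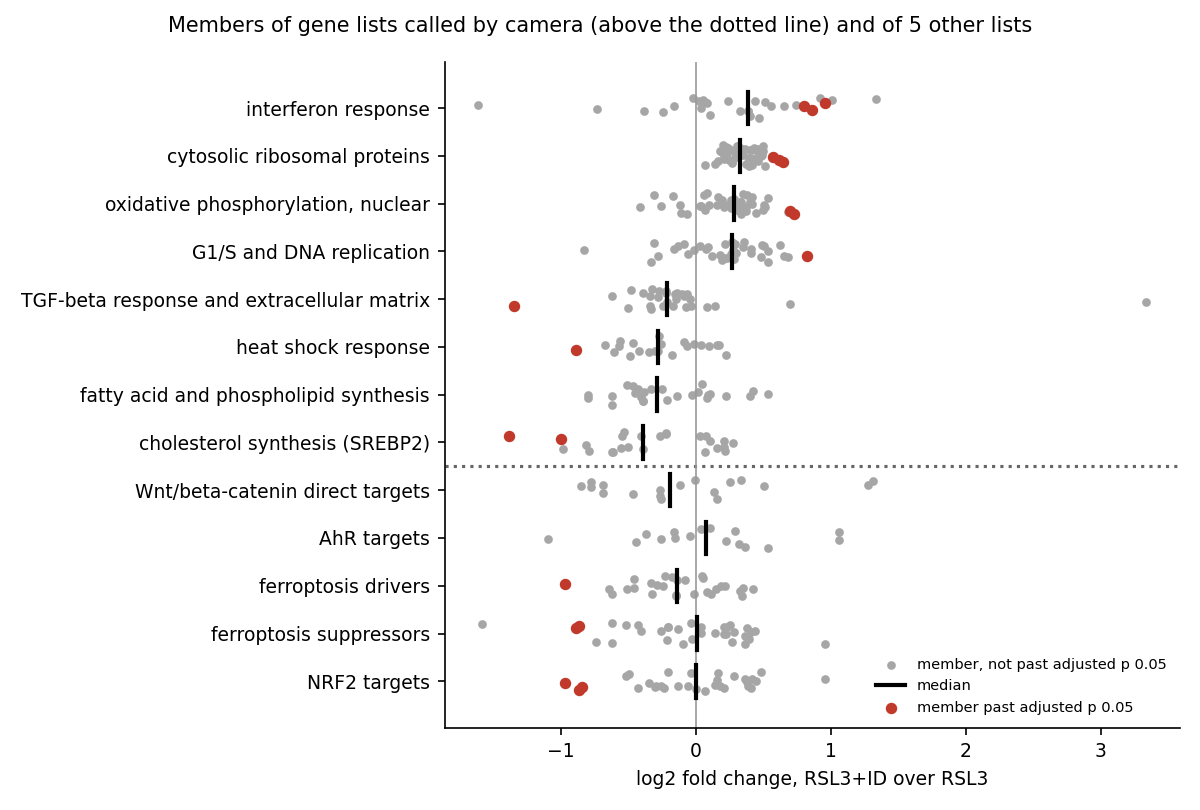
Log2 fold change of RSL3+ID over RSL3 for each tested member of the 8 lists called by camera (above the dotted line) and of 5 other lists, with red points for members past an adjusted p of 0.05 over all genes and a black bar for the list median. The medians run from −0.39 for cholesterol synthesis to 0.39 for the interferon response, while those of the direct Wnt/β-catenin and aryl hydrocarbon receptor targets are −0.19 and 0.07.

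The other 21 lists were not called by camera with all 6 libraries in the main test, but 5 of them were called in at least 1 other setting. In the integrated stress response list of 30 tested genes, ATF4 and the glutamine transporter gene SLC1A5 rose (by 1.70- and 1.49-fold) while TRIB3, a pseudokinase gene induced by ATF4, and JDP2, a bZIP repressor gene named after its values were seen, fell by 1.56- and 1.68-fold; 3 were higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.578). Of 29 p53 targets CDKN1A and PMAIP1, a pro-apoptotic BH3-only gene, rose, the latter by 1.76-fold, and 2 were higher and 2 lower when adjusted over the list alone (0.261). Of 38 genes of G2/M and mitosis CDK1, the mitotic kinase, and CDC25C, the phosphatase that activates it, rose by 1.67- and 1.62-fold, and 3 were higher when adjusted over the list alone (0.956), with a median of −0.09 although camera's direction was up. Its median was 0.13 without RSL3+ID library 2 and 0.10 without RSL3 library 2 but −0.26 without RSL3 library 3, so single libraries set its sign. Of 31 hypoxia and glycolysis genes TPI1, ALDOC and BNIP3, the first 2 being glycolytic enzymes and the last a mitophagy receptor, rose by 1.60-, 1.70- and 1.56-fold and BNIP3L, named after its values were seen, fell 1.62-fold, with 6 higher and 2 lower when adjusted over the list alone (0.177). Without RSL3+ID library 2 this list was called up (median 0.29 against 0.14, adjusted p = 0.00214), while the median was 0.06 without RSL3+ID library 1, 0.04 without RSL3+ID library 3 and 0.05 with scaling to the total count. Of 29 NF-κB and cytokine genes SOD2, the mitochondrial superoxide dismutase, rose from 5591 ± 100 to 8389 ± 470 normalised counts, also when adjusted over the list alone (0.645). Of 31 immediate early genes IER3 rose 1.97-fold, and 2 were higher and 2 lower when adjusted over the list alone (0.578). This list was called up without RSL3+ID library 2 (median 0.14, adjusted p = 0.0467) and down without RSL3+ID library 3 (median −0.31, adjusted p = 0.0150).

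Of 24 genes of the unfolded protein response none passed over all genes and 3 were higher when adjusted over the list alone, with CRELD2 at a log2 fold change of 0.57 (adjusted p = 0.0625, camera 0.0536). Camera called this list up without RSL3 library 1 (0.0358), without RSL3+ID library 2 (0.00354), with no filter on low counts (0.0241) and with upper-quartile scaling (0.0360). Among the settings without a call were scaling to the total count (0.142, median 0.033 against 0.125 in the main test) and the estimated correlation (0.827). Nor was it called without RSL3 library 3 (0.191) or without RSL3+ID library 1 (0.158) or 3 (0.162, median 0.058). Of 31 genes of glutathione and selenoprotein synthesis none passed over all genes and 2 were higher when adjusted over the list alone, with SELENOK at 0.60 (adjusted p = 0.0634, camera 0.0859, and 0.0137 without RSL3+ID library 1). The median of this list was 0.085, or 0.196 without RSL3+ID library 1 and −0.007 with scaling to the total count. Camera gave adjusted p = 0.460 without RSL3+ID library 2 and 0.233 with the length and GC trend removed. None of 30 lysosome and autophagy genes passed over all genes or when adjusted over the list alone, with GABARAPL1 at −0.56 (adjusted p = 0.0717; camera 0.645). Of 26 replication-dependent histone genes H2BC21 fell 2.07-fold, also when adjusted over the list alone (camera adjusted p = 0.181). The histone list was called down without RSL3+ID library 1 (0.0137) or 3 (0.0220) and with the length and GC trend removed (0.00266), and without RSL3+ID library 2 its median turned from −0.19 to 0.09 (0.551). The histone genes deviated from their mean over all libraries by −0.67 in RSL3+ID library 2 and by 0.23 and 0.13 in libraries 1 and 3.

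Among markers of cell types, KRT18, a simple-epithelial keratin, fell 1.58-fold out of 21 tested epithelial markers, with 1 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.238). ZEB2, a repressor of epithelial genes, fell 3.01-fold out of 14 mesenchymal markers, also when adjusted over the list alone (0.393). None of 8 tested endothelial markers passed over all genes or when adjusted over the list alone (0.956), with ERG at −1.46 (adjusted p = 0.182) and 24.9 ± 6.63 against 8.36 ± 2.09 normalised counts. Of 19 immune cell markers 3 had enough reads to test and none passed either way, with CD14 at 0.50 (adjusted p = 0.227).

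By the fixed rule of size, the largest rise was that of SERPINI1, the protease inhibitor neuroserpin, from 32.7 ± 15.8 to 192.9 ± 6.76 normalised counts (log2 fold change 2.63, SE 0.35, adjusted p = 0.0167). The chemokine gene CXCL14, the acylphosphatase gene ACYP1, WNT11, NPPC (the C-type natriuretic peptide), the stress keratin gene KRT16 and the RNA-binding protein gene KHDRBS3 followed, with log2 fold changes of 1.52, 1.48, 1.42, 1.39, 1.36 and 1.33. The largest fall was that of MMP3, the matrix metalloproteinase stromelysin, from 517.9 ± 54.9 to 118.7 ± 31.9 (log2 fold change −2.15, SE 0.24, adjusted p = 0.00880). Among the next largest falls were those of PLCXD2, ZEB2, MSMO1, CREBRF and PMEPA1, with log2 fold changes of −1.61, −1.59, −1.38, −1.37 and −1.34. SERPINI1 (ENSG00000163536) spans chromosome 3 from 167735243 to 167825568 and MMP3 (ENSG00000149968) chromosome 11 from 102835801 to 102843803 on GRCh38, and both are annotated as protein-coding.

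The authors' deposited table of changed genes holds 895 genes, 464 higher and 431 lower in RSL3+ID, and 153 of these with at least a 2-fold difference. All 271 genes called here were among them with the same sign. The remaining 623 tested genes of the authors' deposited table had the same sign here and unadjusted p-values of at most 0.0324. Of the named genes that did not pass here, 7 passed in the authors' deposited table: ACSL4, FOSL1, STC2, SREBF1, CRELD2, SELENOK and GABARAPL1, with adjusted p between 0.0116 and 0.0383. For HMOX1 the authors' deposited table gives a log2 fold change of −0.95, and for FTH1 −0.86.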

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

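TMM and total count scaling, limma-voom, the deposited values as they stand, the removal of the length and GC trend, the test against a fold of 1.5 and, for the gene lists, upper-quartile scaling were chosen after seeing the data. The edgeR, DESeq2 and glmTreat alternatives had been planned for deposited counts and were not run on the log2 values, and limma-voom was used on the recovered reads instead (233 genes). Leaving out mitochondrially encoded genes could move nothing, since none of them was tested. Across the other scalings, filters, pseudocount and tools the count of genes past an adjusted p of 0.05 lay between 203 and 331 and that of genes of at least 2-fold between 61 and 103, except that limma's test against a fold of 1.5 gave 0 and 0 (199 genes at an unadjusted p under 0.05), and the deposited values gave 18 genes of at least 2-fold, since the transform shrinks fold changes. With each library left out in turn these counts ranged from 0 to 1315 and from 0 to 239, and the overlap with the authors' deposited table from 0 to 704. All 271 genes kept their sign and an unadjusted p under 0.05 in each of these 6 fits, which was nearly bound to happen. They had been called on the same libraries, and all 271 were without overlap between the groups. The numbers of the libraries were not treated as pairs, since the deviations of same-numbered libraries correlated at 0.00, −0.25 and −0.18 and 0 of 6 libraries correlated best with their own number. The highest such correlation between the groups was 0.31, for RSL3 library 3 with RSL3+ID library 2. The check covers the column numbers only, and pairs or batches under other numbers were not tested. With the replicate number as a block limma gave 0 genes and 0 of at least 2-fold (1993 at an unadjusted p under 0.05), while camera called 8 lists as before.

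Camera called 0 lists with an estimated correlation, and fry called 0. For the other settings between 6 and 10 lists were called, against 8. With 1 library left out the log2 fold change of AXIN2 ranged from −0.10 to 0.55 and that of TFRC from −0.02 to 0.56, the median of the immediate early genes from −0.31 to 0.14 and that of the TGF-β list from −0.37 to 0.046. The reversals came with RSL3 library 3 or RSL3+ID library 1 or 3 left out for AXIN2, RSL3+ID library 1 for TFRC, and RSL3+ID library 2 for both lists, and the cause was not tested. Over all settings and the 64 named genes, 904 results kept their side of the threshold, 350 lost it with the same sign, 19 gained it and 4 changed sign. At a depth of 15206183 to 18506637 reads, genes as low as CYP1A1 or LEF1 carry wide intervals. The 95% interval of the log2 fold change ran from 0.08 to 2.04 for CYP1A1 and from 0.22 to 2.33 for LEF1. Without adjustment for the number of genes, both intervals lay above 0, and both included a 2-fold change. Neither gene passed the limma test over all genes (adjusted p = 0.222 and 0.183).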

Other observations

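The tests on principal transcript length, the comparison with matched genes in each library, the tests on the β-catenin and aryl hydrocarbon receptor sets with their adjustment over both, and the genes named in this paragraph were chosen after the results had been seen. The growth factor receptor gene EGFR fell 2.44-fold, from 746.6 ± 64.4 to 306.6 ± 45.3 normalised counts (n = 3 per group, limma adjusted p = 0.0167), and the neurotrophin receptor gene NGFR rose 2.06-fold (adjusted p = 0.0167).

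Camera called the ribosomal protein and respiratory chain lists higher in RSL3+ID, though not with an estimated correlation (adjusted p = 0.525 and 0.635), and limma's fry called neither (adjusted p = 0.0610 and 0.154). Against 10000 random lists matched on exon length and expression the medians of 0.33 and 0.29 lay at percentiles 99.99 and 99.42, and with the principal transcript length at 99.98 and 99.86, but such draws take genes as independent, while the members had estimated correlations of 0.328 and 0.309. With the level of the matched genes subtracted in each library, the ribosomal list still differed between the groups by 0.22 on the log2 scale (95% confidence interval 0.15 to 0.30, and 0.14 to 0.31 with the principal transcript length), so the length trend does not account for the whole of that shift, while an effect of the treatment stays open, as does a difference in RNA quality or library preparation, for which the labels give no value. The respiratory chain list differed by 0.13 (−0.06 to 0.31), and by 0.17 (−0.08 to 0.41) with the principal transcript length, so the length trend may account for its shift. Its members deviated by −0.02 and 0.02 in RSL3 library 3 and RSL3+ID library 1, where deviation and exon length correlated at −0.01 and −0.02, and by −0.23 and 0.21 in RSL3 library 2 and RSL3+ID library 2, with correlations of 0.29 and −0.22.

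FTH1, HMOX1, HSPB1 and MT2A were lower in RSL3+ID. With the length and GC trend removed the t closest to 0 among the 4 genes was −6.07, and with any 1 library left out it was −4.23. All 4 estimates were more negative with that trend removed (FTH1 −1.02 against −0.86, MT2A −1.19 against −1.01). This was likely from their lengths, since the 4 genes have exon lengths from 1299 to 2405 bp. Among genes in the shortest of 5 groups by exon length (median 1922 bp) the median log2 fold change was 0.17. The length trend thus ran against the falls and does not account for them. Without 1 library the estimates lay between −1.085 and −0.763. All 271 called genes kept an unadjusted limma p under 0.05 in those fits. A called gene could therefore hardly fail that check, which excludes little about single libraries. HSPB1 and MT2A were picked because they passed the test, and FTH1 and HMOX1 were the always-named genes that passed it. This favours such a result for all 4 genes. An effect of indirubin stays open, as does whether the falls belong to a wider response, and a difference between cultures or their density was not tested.

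The hypothesis that indirubin raised β-catenin transcription was tested on 9 measured feedback targets out of 13. 6 had positive estimates, with a median log2 fold change of 0.26, and limma's fry gave an adjusted p = 0.574 over both sets tested. The members went both ways, from −0.85 for NOTUM to 1.32 for APCDD1, so the test neither shows nor excludes activation at 24 h. The hypothesis that indirubin may have activated the aryl hydrocarbon receptor was tested on CYP1A1, CYP1B1, AHRR, TIPARP, NQO1 and ALDH3A1. 5 of 6 had positive estimates, with a median of 0.33, and limma's fry gave 0.0499 before adjustment and an adjusted p = 0.0997 over both sets, so it did not pass. None of the 6 genes passed the limma test over all genes.

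The real grouping of the libraries gave 271 genes, and the highest count among the other 9 ways to split 6 libraries into 3 and 3 was 0, so 1 of 10 splits gave as many. With 10 splits the share cannot fall under 0.1, too few for a share under 0.05.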
